A study of Mus musculus with 6 samples.

How the data were processed

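Expression was measured in 6 adult mouse hearts, 3 knockout and 3 wild-type, on single-colour Illumina bead arrays. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column with DNase I treatment, and turned into biotin-labelled cRNA. Samples were grouped by their titles, each of which names a line, a genotype and, for the heart-specific line, a sex. Each wild-type title names the knockout it is the control of, which gave 3 pairs. No label states whether hearts of different arrays came from separate animals, apart from the differing sexes, so p-values measure only the spread between these samples, which may be technical.

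The deposited intensities were made by the authors with GenomeStudio, per the labels, and its version, background option and normalization option are not given in the sources used here. The deposited values are on a linear scale from 82.48 to 50962.29, with medians of 117 on all 6 arrays. The sorted values of the 6 columns differed by at most 2.31%, so the authors' intensities were taken as quantile-normalized between arrays, and they show no sign of background subtraction. A background left in compresses the fold changes of dim genes. A second deposited table of signals and detection p-values has 12 columns headed by numbers that match no label, so they were given to no sample and not used here. The planned background correction and detection p-values depended on that table. In their place the log2 of the deposited normalized intensities, planned as an alternative, became the measure, with no further normalization.

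Probe names were taken from the platform annotation supplied for this work. It gives 1 gene for 34885 probes, several for 18 and none for 10378. Of its entries, 34807 matched the gene IDs of the mouse annotation GRCm38.p6, which was used only for symbols and for the order of genes along chromosomes, since the sources used here name no build. Expression above background was judged against 1526 probes of olfactory, vomeronasal and trace amine receptor genes. The background level of an array was the 95th percentile of these probes (121 to 124), and probes above it on at least 2 of 6 arrays were kept (21016). A gene was represented by its brightest kept probe, and 4342 of the 11285 genes had several kept probes, which can differ. A fold is given as at least N-fold where a gene was at or below background on all arrays of the dimmer group, taking the higher of the background level and the measured value there.

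Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) and Benjamini-Hochberg adjustment over all genes kept, at an adjusted p under 0.05. The comparison over 3 pairs had the pair as a block and left 2 residual degrees of freedom, with a prior of 5.30. A second fit with separate knockout terms for the general and the heart-specific line gave the heart-specific effect and the difference between lines, with 1 residual degree of freedom and a prior of 5.74. The sex comparison used the 4 arrays of the heart-specific line with genotype as a term. Pairing comes from the titles. Deviations from the genotype means correlated across genes within each pair (r = 0.34, 0.33 and 0.35). An exact test by sign flips of the 3 pairs cannot give a two-sided p below 0.25, nor a permutation of 3 against 3 arrays one below 0.1. Gene-level p-values therefore rest on the model. The general pair was described by log2 differences of at least 1 in genes above background on at least 1 of its arrays.

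Gene lists for pathways, chromatin and markers of other cell types were fixed before the data were examined. Of these lists, 31 had at least 5 measured genes and were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry. For the general pair, the median of each list was placed among 10000 random lists of the same size matched on mean expression. The difference between lines was tested on lists with camera only after the data were seen.

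The genes named were chosen by a rule fixed before the data were examined. It takes Kdm4a, Fhl1, Nppa, Nppb, Myh7, Myh6 and Acta1 in each knockout comparison. For the 3 pairs it takes up to 12 genes per direction past the test with the same sign in every pair, filled up with genes not past it that have the largest smallest difference, and for the heart-specific pairs up to 8 likewise. For the general pair it takes the 8 largest differences per direction among genes above background on both arrays and 4 among genes above it on 1 array. It further takes sex-linked genes and the 6 largest autosomal or unplaced genes per direction past the sex test, the 6 largest per direction past the test between lines, and up to 4 members of each list described. Predicted gene models were counted and not named. Genes singled out for their place on the chromosome of Kdm4a, and Fcer1g and Tubb1 in the test between lines, were named after their values were seen.

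The fits were tested on simulated data in 20 runs with 200 of 11285 genes changed. Genes changed by 1 on the log2 scale were recovered in 93.1% of cases over 3 pairs, 71.9% in the heart-specific comparison, 2.91% in the difference between lines and 72.5% between sexes. For a change of 2, the difference between lines recovered 62.4%. Many changed genes make the adjusted threshold easier to pass, so these shares are no estimate for data with few changes. Alternatives covered background correction on the receptor probes, the offset, the filter, the probe of a gene, the spread model, the block, left-out pairs, the set test and thresholds. Slide and scan information is not used here. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.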

Results

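Gene expression was measured in adult mouse hearts lacking Kdm4a (also called Jmjd2a), a demethylase of histone H3 lysines 9 and 36, and in their wild-type controls. Total heart RNA was hybridised to 6 single-colour Illumina bead arrays that form 3 pairs of a knockout and a wild-type heart. In the general line there was 1 knockout and 1 wild-type array, without a stated sex. In the heart-specific line there were 2 knockout and 2 wild-type arrays, with a female pair and a male pair. On each array 18307 to 19658 of the 45281 probes (40.4% to 43.4%) lay above the background level, and 11285 genes entered the tests. The small number of arrays limits the precision of every value. All differences are log2 knockout minus wild type unless another direction is stated.

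The targeted transcript could not serve as a check of the labels, because none of its 3 probes gave a usable signal. The brightest Kdm4a probe had an intensity of 115 in the general wild type and 102 in the general knockout, 119 and 107 in the female pair, and 123 and 114 in the male pair. It was lower in the knockout of all 3 pairs, by -0.15 ± 0.04 (SD, n = 3 pairs; limma adjusted p = 0.999 over 19057 unfiltered genes), but it exceeded the background level on only 1 array. The other 2 probes were below background on all 6 arrays, and nothing in the sources used here places any of the probes inside or outside the deleted part.

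The comparison of heart-specific knockout with wild-type hearts asked which genes differ when Kdm4a is removed from the heart. The largest difference in this comparison was in Hspb7, a small heat shock protein abundant in heart muscle, whose intensity was 3947 in the wild-type and 430 in the knockout female heart, and 2770 and 564 in the male hearts. Its difference was -2.75 ± 0.64 (SD, n = 2 pairs), and it missed the threshold (adjusted p = 0.0639). Pdlim3, a LIM-domain protein of the muscle Z-disc, differed by -1.48 in the female and -0.996 in the male pair (adjusted p = 0.355). Klhl21, an adaptor of a Cul3 ubiquitin ligase, differed by -1.02 and -0.98 (adjusted p = 0.355). The guanine nucleotide exchange factor Arhgef19 had differences of -0.89 and -1.42, and Ppargc1a, a coactivator of mitochondrial biogenesis, of -0.75 and -0.57. Cd300lg differed by -0.86 and -0.65, Sub1 by -0.60 and -0.63, and Dct, an enzyme of melanin synthesis, by -0.60 and -0.57, with a male knockout signal below background.

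**Figure D1:**
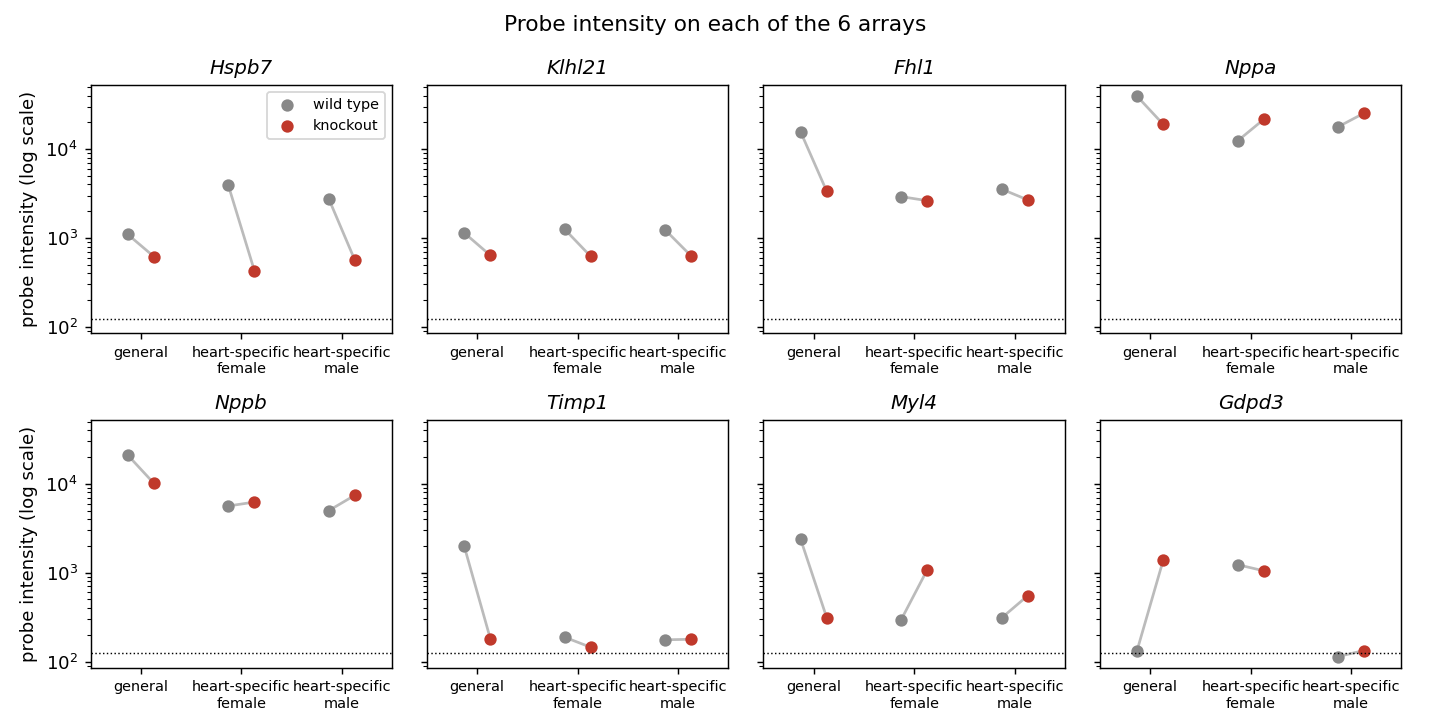
Probe intensity (vertical axis, log scale) of 8 genes on the 6 arrays, with the wild-type (grey) and knockout (red) heart of each pair joined by a line and the highest of the background levels dotted. Hspb7 and Klhl21 lay lower in the knockout of every pair, whereas Fhl1, Timp1 and Nppb were brightest in the general wild-type heart.

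Among genes with higher signal in both heart-specific knockouts, Nudt6 had the largest mean (2.23 in females and 1.08 in males), and Ccdc124 differed by 1.08 and 1.03. The atrial light chain gene Myl4 differed by 1.87 and 0.83, and 2 genes of red cell precursors were also higher, Alas2 by 0.72 and 1.12 and the anion exchanger Slc4a1 by 0.65 and 0.65, with a female wild-type signal below background. Mfap4 (0.87 and 0.68) and Pnpla3 (0.63 and 0.92) completed the group, with the interferon-inducible Ifi27l2a, whose intensity was 949 in the wild-type and 1434 in the knockout female heart and 859 and 1974 in the male hearts. Of the cardiac stress genes fixed in advance, the natriuretic peptide gene Nppa was higher in both knockouts (0.80 and 0.51) and so was Nppb (0.15 and 0.57). Nppa is also an atrial marker, and 5 of 9 atrial markers were higher in both knockouts and 1 lower in both. Whether uneven atrial tissue raised Nppa in these hearts was not tested. Fhl1, a LIM-domain protein of stressed myocardium, had differences of -0.15 and -0.40. The skeletal actin gene Acta1 differed by 0.37 in the female and -1.41 in the male pair, the fetal myosin gene Myh7 by 0.16 and -0.38, and the adult myosin gene Myh6 by -0.02 and -0.25. Myh6 signals of 36105 to 43993 on the 6 arrays lay near the highest value on the arrays (50962), where differences can be hidden, and so did Nppa in the general wild type (39341).

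With limma, 0 of 11285 genes passed an adjusted p of 0.05 in the heart-specific comparison, and 505 had an unadjusted p under 0.05 where chance gives about 564. Hspb7 passed in 4 alternative settings, with adjusted p from 0.00131 to 0.0923 over 7 settings with 1 value per gene. With every probe on its own, no probe passed (smallest limma adjusted p = 0.116). Pdlim3 passed only when a gene's probes were averaged (adjusted p = 0.0492, and up to 0.645 in the others).

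Of 19 measured interferon response genes, 16 were higher in both knockouts and 0 lower in both, with a list mean of 0.28 in females and 0.31 in males. Isg15, a ubiquitin-like modifier, was higher by 0.53 ± 0.01 (SD, n = 2 pairs), Psmb8 by 0.47 ± 0.33 and the antiviral gene Oasl2 by 0.47 ± 0.08. The list shifted upward with camera at its preset correlation (adjusted p = 9.49e-10; adjusted p = 0.925 with an estimated correlation), and 8 members passed when adjusted over the list alone against 0 over all genes. The 12 antigen presentation genes shifted upward as well (adjusted p = 0.00169; adjusted p = 0.925 with an estimated correlation), with 6 higher in both pairs and 0 lower. Examples are the class I genes H2-D1 (0.40 ± 0.11, SD, n = 2 pairs) and H2-Q7 (0.40 ± 0.05) and B2m (0.39 ± 0.07). Macrophage markers, measured in the same hearts, had a mean of 0.06 in the female and 0.15 in the male pair and did not pass (adjusted p = 0.0933).

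Fatty acid oxidation genes shifted downward in the heart-specific knockouts, with 12 of 29 members lower in both pairs and 2 higher (adjusted p = 3.38e-05; adjusted p = 0.925 with an estimated correlation). The acyl-CoA thioesterase Acot1 had differences of -0.49 in females and -0.52 in males, and the dienoyl-CoA reductase Decr1 of -0.31 and -0.63. Only 1 member, Ppargc1a, a regulator and not an enzyme of the pathway, passed when adjusted over the list alone, against 0 over all genes. The 9 atrial markers shifted upward (adjusted p = 0.0106; adjusted p = 0.925 with an estimated correlation), led by Myl4 and Nppa, as did the 7 red blood cell markers (adjusted p = 0.0103; adjusted p = 0.925 with an estimated correlation), led by Alas2 and Slc4a1, and in each of these lists those 2 members passed when adjusted over the list alone. The red cell list had a mean of 0.35 in the female and -0.05 in the male pair, where the globin gene Hbb-b2 differed by -2.34, and its call was lost with background correction at offset 16 (adjusted p = 0.068). The 35 ribosomal protein genes passed too (adjusted p = 5.16e-05; adjusted p = 0.925 with an estimated correlation), but their mean was 0.39 in the male and -0.05 in the female pair. The remaining 25 of 31 tested lists did not pass, with TCA cycle and unfolded protein response genes nearest to the threshold (adjusted p = 0.0523 for both). Neither an estimated correlation nor fry left any list past the threshold in this comparison. With 1 residual degree of freedom hardly any list could pass these tests, so this decides little about the lists called at the preset correlation.

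Several genes with the widest differences in both heart-specific pairs lay on the chromosome that carries Kdm4a (gene order of GRCm38.p6). Of the 50 genes with the largest difference shared by both pairs, 10 were on this chromosome, which holds 682 of the 11266 placed genes and would hold 3.03 of 50 by its share. These were Hspb7, Arhgef19, Klhl21, Fbxo44, Acer2 and Ctnnal1, lower in the knockouts, and Nppa, Tmem51, Pde4b and Isg15, higher. Among the 100 tested genes nearest to Kdm4a, 50 on each side, 0 belonged to the 50 most changed. Hspb7 lay 223 tested genes from Kdm4a and Klhl21 286. Both lay after Kdm4a in gene order, as did Arhgef19, Tmem51, Nppa, Fbxo44 and Isg15, in a stretch 221 to 335 tested genes away. Pde4b, Acer2 and Ctnnal1 lay before it, 87, 125 and 185 tested genes away. The chromosome was looked at after the values were seen, and 12 of the 100 most changed genes lay on it.

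**Figure D2:**
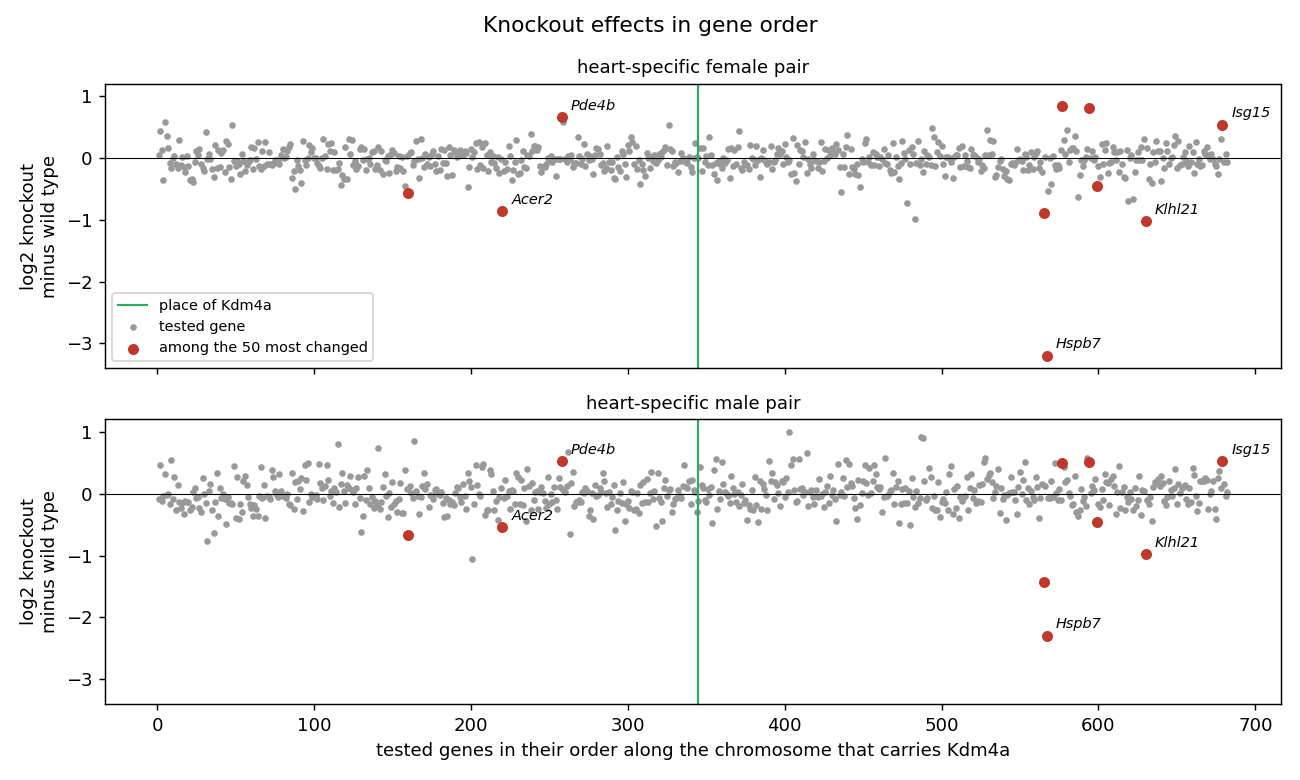
Log2 difference, knockout minus wild type (vertical axes), of 682 tested genes in their order along the chromosome that carries Kdm4a (horizontal axis), in the heart-specific female (top) and male (bottom) pair. Red points are the 10 genes among the 50 most changed in both pairs, grey points all other genes and the green line the place of Kdm4a, next to which no red point lies.

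Across all 3 pairs the question was which genes depend on Kdm4a whatever the line. Klhl21 was lower in every pair, at -0.95 ± 0.09 (SD, n = 3 pairs), with an intensity between 1144 and 1253 in the wild-type and between 619 and 637 in the knockout hearts (adjusted p = 0.312). Hspb7 was lower in all 3 pairs (-2.11 ± 1.196), by less in the general pair (-0.83). Its wild-type intensity was 1098 in the general pair against 3947 and 2770 in the female and male pairs. Its knockout intensities of 618, 430 and 564 lay closer together. The antioxidant enzyme gene Gpx3 differed by -0.52 ± 0.13, the mitochondrial outer membrane gene Fundc2 by -0.56 ± 0.17 and the actin regulator Cyfip2 by -0.57 ± 0.14. The kinase gene Riok3 (-0.67 ± 0.40), Spcs3 of the signal peptidase (-0.57 ± 0.23), Dct (-0.53 ± 0.09), Epb41l4a (-0.50 ± 0.14), Ttc27 (-0.42 ± 0.10), the nucleotide-sugar transporter family gene Slc35f5 (-0.39 ± 0.04) and Cd99l2 (-0.34 ± 0.01) were lower in every pair too.

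Higher in the knockout of every pair were Mrps27, a protein of the mitochondrial ribosome (0.60 ± 0.03, SD, n = 3 pairs), and the interferon-induced kinase gene Eif2ak2 (0.75 ± 0.41). The N-cadherin gene Cdh2 (0.77 ± 0.37, with the male wild type below background), Isg15 (0.48 ± 0.09), the DNA repair gene Mgmt (0.53 ± 0.25) and the D-aspartate oxidase gene Ddo (0.61 ± 0.38) were also higher. Smaller differences of this direction were seen for Cmtm8 (0.46 ± 0.15), the transcriptional coactivator Ppargc1b (0.42 ± 0.14), the calcium/calmodulin-dependent kinase gene Camk2d (0.39 ± 0.09), Gipc2 (0.39 ± 0.12), Phf11d (0.37 ± 0.05) and the mitochondrial gene Opa3 (0.32 ± 0.01). None of these genes passed the test, and apart from Klhl21 each had an adjusted p of 0.9998. The mean of Fhl1 (-0.93 ± 1.13) held a difference of -2.22 in the general pair, and that of Acta1 (-0.98 ± 1.19) differences of -1.90 in the general and -1.41 in the male pair. The remaining means were those of Nppa (0.09 ± 0.998), Nppb (-0.11 ± 0.84), Myh7 (-0.19 ± 0.31) and Myh6 (-0.08 ± 0.15). Without the general pair Nppb became 0.36, without the female or the male pair Nppa became -0.27 or -0.12, and without the male pair Myh6 became 0.00568.

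With limma and the pair as a block, 0 of 11285 genes passed an adjusted p of 0.05 over 3 pairs, and 303 had an unadjusted p under 0.05 against about 564 by chance. In simulated data of this design with 200 genes changed at once, 93.1% of those changed by 1 on the log2 scale in every pair were recovered. For a change of 0.5 this was 13.1%. Many changed genes make the adjusted threshold easier to pass, so these shares do not carry over to data with few changes. Klhl21, at -0.95 ± 0.09 (SD, n = 3 pairs), did not pass with limma (adjusted p = 0.312).

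Interferon response genes shifted upward over the 3 pairs as well, with 9 of 19 members higher in every pair and 0 lower in every pair (list mean 0.20 ± 0.16, SD, n = 3 pairs; adjusted p = 1.37e-07 with camera; adjusted p = 0.886 with an estimated correlation). Isg15, Oasl2 (0.37 ± 0.18), Oas2 (0.35 ± 0.15) and Bst2 (0.35 ± 0.16) had the largest means, and 1 member, Isg15, passed when adjusted over the list alone against 0 over all genes. In the general pair the list mean was 0.01, against 0.28 in females and 0.31 in males, and that pair's macrophage marker mean was -0.30. The call held without each pair in turn (adjusted p up to 0.00366).

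A further 5 lists passed over 3 pairs at the preset correlation, each with an adjusted p of 0.886 with an estimated correlation, and each was lost without at least 1 pair. Antigen presentation genes (adjusted p = 0.0361; 2 of 12 higher in every pair, such as H2-Ab1 at 0.36 ± 0.27) were higher, and the call ended without the female (0.0869) or the male pair (0.72). Oxidative phosphorylation genes (adjusted p = 0.0338; 10 of 55 higher in every pair, such as Ndufa2 at 0.34 ± 0.21) were higher, and the call ended without the general (0.149) or the male pair (0.227). Fatty acid oxidation genes (adjusted p = 0.0338; mean 0.08 in the general pair, -0.19 in females and -0.18 in males) were lower, and the call ended without the female (0.45) or the male pair (0.339). Circadian clock genes (adjusted p = 0.0361; 4 of 14 lower in every pair, such as Nr1d2 at -0.40 ± 0.20 and Tef at -0.36 ± 0.23) were lower, and the call ended without the general (0.0933) or the female pair (0.23). Hypertrophy and fetal genes were lower (adjusted p = 0.0338), with a mean in the general pair of -0.76, in females of 0.17 and in males of 0.03, and without that pair the direction turned (adjusted p = 0.485). The other 25 lists did not pass (adjusted p from 0.0889 to 0.983), and fry called 0 lists. With 2 residual degrees of freedom, neither fry nor an estimated correlation could have called many. With background correction at offset 16 the interferon list alone passed, and at offset 50 the interferon and the hypertrophy list. Without the pair block, interferon response, oxidative phosphorylation and fatty acid oxidation passed (3 lists).

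**Figure D3:**
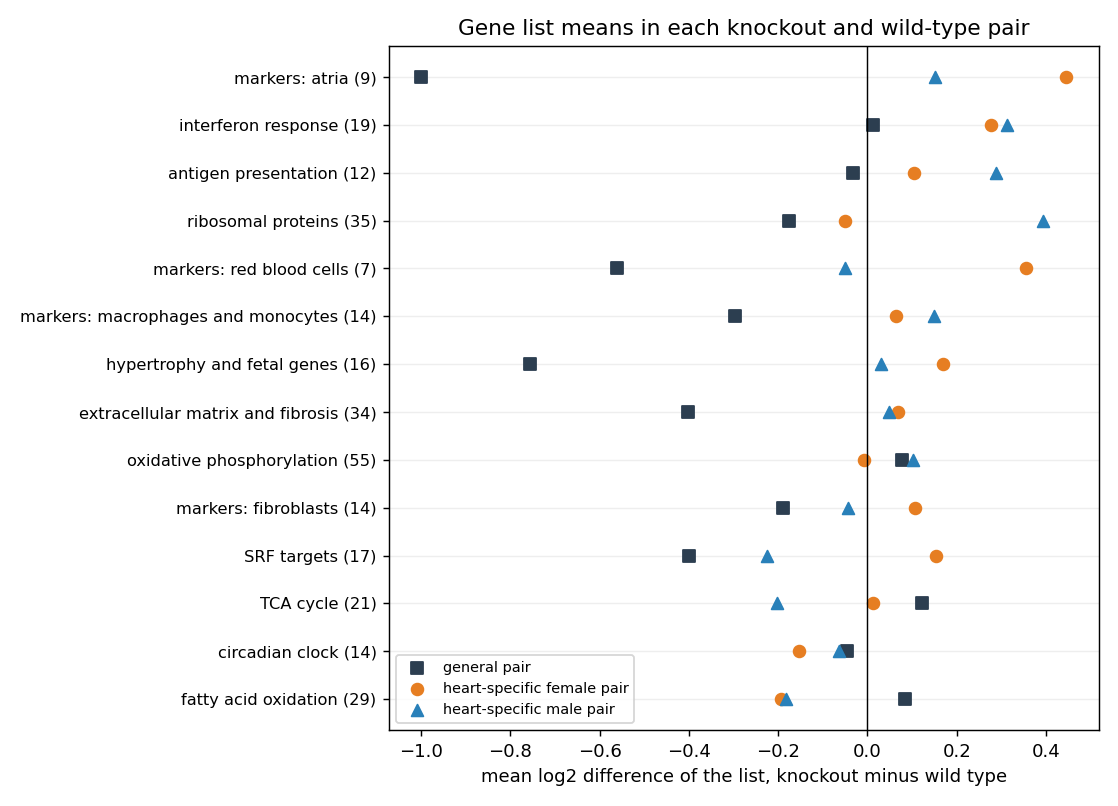
Mean log2 difference, knockout minus wild type (horizontal axis), of 14 gene lists in the general (squares), heart-specific female (circles) and heart-specific male pair (triangles), with the number of measured genes in brackets. Atrial markers and hypertrophy genes had means of -0.999 and -0.76 in the general pair and above 0 in both other pairs, while interferon response genes had means of 0.28 and 0.31 in the heart-specific pairs and 0.01 in the general pair.

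Knockout effects of different pairs had correlations below or near 0 across genes. Across 11285 genes, which are not independent replicates, the Pearson correlation of the differences was -0.17 between the general and the female pair, -0.08 between the general and the male pair and -0.01 between the female and the male pair (Spearman -0.12, -0.08 and -0.01). No array was shared between pairs. In all, 2461 genes (21.8%) had the same sign in all 3 pairs, against 25% by chance.

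In the general pair the comparison concerned loss of Kdm4a outside as well as inside the heart, as far as the word general in its label says, and had 1 array per genotype and so no replicate check. The wild-type heart had far higher signal than the knockout for Timp1, an inhibitor of matrix metalloproteinases (1995 against 182, a difference of -3.46), and for the platelet chemokine gene Ppbp (1176 against 134, -3.14). The atrial light chain Myl4 (-2.94), Slc4a1 (-2.41), the lysosomal protease gene Ctsc (-2.25), Fhl1 (15637 against 3347, -2.22), the uridine-cytidine kinase gene Uck2 (-2.16) and the neutrophil lipocalin gene Lcn2 (-1.98) followed. Signal above background in the wild-type heart alone was found for Myl7 (at least 5.08-fold higher there), the platelet tubulin gene Tubb1 (at least 4.29-fold), Fcer1g (at least 4.25-fold) and the muscle ankyrin repeat gene Ankrd2 (at least 3.15-fold). Of the other stress genes, Acta1 differed by -1.90, Nppa by -1.05, Nppb by -1.05 and Myh7 by -0.36, and Myh6 by 0.03, or -0.34 as the mean of its probes.

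Higher in the general knockout were Gdpd3 (133 in the wild type and 1378 in the knockout, a difference of 3.37) and Timp4, another inhibitor of metalloproteinases (1.67). The glutathione-degrading enzyme gene Chac1 (1.60), the cyclin gene Ccng2 (1.56), Ddit4, an inhibitor of mTORC1 signalling (1.37), the tyrosine catabolism gene Fah (1.25), the ketone body enzyme gene Bdh1 (1.16) and the potassium channel subunit gene Kcnip2 (1.14) were higher too. Stbd1 exceeded background in the knockout alone (at least 3.06-fold), as did Stk35, Morn3 and Vsnl1 (at least 1.25-, 1.25- and 1.14-fold). At the chosen size of 2-fold, 65 of 10681 genes differed, 16 higher and 49 lower in the knockout. Background correction with an offset of 16, which widens differences of dim genes, gave 313, with 121 higher and 192 lower.

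Of the 49 genes at least 2-fold lower in the general knockout, 10 belonged to the hypertrophy or the matrix list. Of 16 measured hypertrophy and fetal genes 15 were lower, 6 of them at least 2-fold, such as Fhl1, Acta1, Ankrd1 (-1.49) and Ccn2 (-1.16), and the list median of -0.59 lay at percentile 0 of 10000 random lists matched on expression. Of 34 extracellular matrix genes 26 were lower, with Timp1, Tnc (354 in the wild type and 111, below background, in the knockout), Ccn2 and Col3a1 (-1.11) among the 5 that were at least 2-fold lower (median -0.24, percentile 0). Fibroblast markers had a median of -0.12 (percentile 2.45; 9 of 14 lower). Atrial markers had a median of -0.92 (percentile 0; 6 of 9 lower), SRF targets of -0.18 (percentile 0.11) and ribosomal protein genes of -0.15 (percentile 0). Macrophage markers had a median of -0.17 (percentile 0.45; 12 of 14 lower), neutrophil and mast cell markers of -0.31 (percentile 0.06; S100a9 -1.45 and S100a8 -1.18), and red cell markers had a median of -0.29 (percentile 0.38; 4 of 7 lower). Glycolysis genes lay toward the other end, with a median of 0.19 (percentile 97.4; 11 of 17 higher). Toward the low end also lay circadian clock genes (median -0.12, percentile 1.96, 10 of 14 lower). Natriuretic and adrenergic signalling genes did as well (median -0.11, percentile 1.51, 11 of 16 lower). These percentiles describe 2 arrays and not the genotypes.

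With the general line at 1 pair and the spread taken from the heart-specific pairs, 9 genes passed a test of the knockout effect between lines. Myl4 (difference of effects -4.29 ± 0.41, SE; adjusted p = 0.0386), Ppbp (-3.38 ± 0.23; 0.0171), Timp1 (-3.28 ± 0.26; 0.0171), Slc4a1 (-3.07 ± 0.22; 0.0171), and Alas2 (-2.80 ± 0.26; 0.0367) had a lower effect in the general than in the heart-specific pairs. Myl7 (adjusted p = 0.0497), Fcer1g (0.0434) and Tubb1 (0.0497) complete the 8 genes of this direction, but their general knockout signal was below background, and Myl7 and Tubb1 were below it on 3 of the 4 heart-specific arrays as well, so the size of their difference is not known. Gdpd3 was the 1 gene of the other direction (3.38 ± 0.27; 0.0171). Ppbp and Slc4a1 in the female wild type and Gdpd3 in the male wild type were below background too, which limits their heart-specific effect. Both general hearts had the sex-linked signals of males, whereas the heart-specific effect is the mean of a female and a male pair. Line and sex are therefore not fully separated here. Fhl1 fell short (-1.95 ± 0.24; adjusted p = 0.0653), as did Nppa (-1.71 ± 0.24; adjusted p = 0.112). The fit assumed that the lone general pair varied like the heart-specific pairs, with 1 residual degree of freedom, and 725 genes had an unadjusted p under 0.05 against about 564 by chance. The count moved from 0 to 28 between settings, and was 0 among the 8573 genes above background on all 6 arrays.

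Female and male hearts of the heart-specific line were told apart by their sex-linked transcripts. Xist, the RNA of the inactive X chromosome, had a mean intensity of 1589.5 in the 2 female hearts and was at background in the males (at least 13.1-fold higher; adjusted p = 0.000186), and Eif2s3y of the Y chromosome was at least 10.5-fold higher in males (adjusted p = 0.00721). Kdm5d, a Y-linked demethylase gene, was at least 1.65-fold higher in males (adjusted p = 0.117, and from 0.0132 to 0.0325 in 4 other settings), and Uty differed by -0.48 ± 0.15 (female minus male, SE; adjusted p = 0.336). Besides these, Gdpd3 (3.21 ± 0.15; adjusted p = 0.00128) and Paip1 (1.85 ± 0.13; 0.00766), a partner of the poly(A)-binding protein, were higher in both females. Ctsc (-2.93 ± 0.20; 0.00741) and the lipid hydrolase gene Pnpla3 (-1.80 ± 0.14; 0.00955) were higher in both males. In all, 3 genes were higher in females and 3 in males with limma.

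Matrix genes were lower in female than in male hearts, with a mean difference of -0.35 over 34 genes (adjusted p = 3.26e-11 with camera; adjusted p = 0.664 with an estimated correlation) and 15 members past the test when adjusted over the list alone against 0 over all genes. Sparc (-0.98 ± 0.14, SE), Col4a1 (-0.89 ± 0.14), Col1a1 (-0.82 ± 0.16) and Col8a1 (-0.81 ± 0.13) had the largest differences. Macrophage markers (mean -0.35; adjusted p = 4.18e-07), antigen presentation genes (-0.27; 0.000493), interferon response genes (-0.22; 0.000285), endothelial markers (-0.23; 0.00369) and cell cycle genes (-0.12; 0.00361) were lower in females, each with an adjusted p of 0.664 with an estimated correlation. Red cell markers (-0.29; 0.00176), hypertrophy and fetal genes (-0.22; 0.00361) and glycolysis genes (-0.20; 0.00361) were lower with the same p of 0.664 under an estimated correlation, and TCA cycle genes (-0.17; 0.0111) with 0.676. Ribosomal protein genes were higher in females (0.30; 2.23e-07), with Rpl30 at 1.05 ± 0.14 and Rps15 at 0.73 ± 0.19. Immediate early genes (0.20; 0.00361), atrial markers (0.26; 0.0114), oxidative phosphorylation genes (0.09; 0.0341) and oxidative stress genes (0.15; 0.04) were also higher, and these 5 lists each had an adjusted p of 0.664 with an estimated correlation. With background correction the calls of oxidative phosphorylation (adjusted p = 0.214 at offset 16 and 0.095 at offset 50) and oxidative stress genes (0.116 and 0.0656) were lost, as was that of TCA cycle genes at offset 16 (0.0605), and nerve and Schwann cell markers came to pass (0.00821 and 0.0423). In this comparison 15 of 31 lists passed at the preset correlation, 0 with an estimated correlation and 0 with fry. The few residual degrees of freedom left a list little chance to pass the latter tests. With 2 hearts of each sex, the sex difference cannot be separated from other differences between those hearts.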

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

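The list tests of the difference between lines, and the tests of array distance and of atrial markers with the bounds that decide them, were chosen only after the results were seen. The test of globin genes was set before its values were seen.

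A test of the difference in knockout effect between the general and the heart-specific line marked 9 genes, with 1 general pair, no replicate of it and the spread taken from the heart-specific pairs, and the count ran from 0 to 28 across settings. The general effect minus the heart-specific effect on the log2 scale was -4.29 for Myl4, -3.38 for Ppbp, -3.28 for Timp1, -3.07 for Slc4a1, -2.80 for Alas2, -2.56 for Myl7, -2.23 for Fcer1g, -2.18 for Tubb1 and 3.38 for Gdpd3. For Myl7, Fcer1g and Tubb1 these are fitted values and no measured sizes, because their general knockout signal was below background, as were those of Myl7 and Tubb1 on 3 of the 4 heart-specific arrays. The same test on gene lists at camera's preset correlation marked 12 lists, and 9 or 11 with background correction at offset 16 or 50, where antigen presentation was lost at both (adjusted p = 0.101 and 0.0522) and fibroblast markers (0.073) and TCA cycle genes (0.067) at offset 16. Mean differences were -1.30 for atrial markers, -0.86 for hypertrophy and fetal genes, -0.71 for red cell markers (median 0.06, so the mean rests on Slc4a1 and Alas2), -0.46 for extracellular matrix genes and -0.40 for macrophage markers. They were -0.36 for SRF targets, -0.35 for ribosomal protein genes, -0.28 for interferon response genes, -0.23 for antigen presentation genes and -0.22 for fibroblast markers, and on the other side 0.27 for fatty acid oxidation and 0.22 for TCA cycle genes. With an estimated correlation none of the 12 passed (adjusted p = 0.857 to 0.858).

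Acta1 and Myh7 had differences of opposite sign in the female and the male heart-specific pair. The female minus the male effect was 1.78 for Acta1 and 0.54 for Myh7. These differences were not tested, since there is 1 pair of each sex.

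For most of the genes at least 2-fold apart in the general pair, the wild-type heart stood farther from the heart-specific hearts than the knockout heart did. In 53 of the 65 genes, a share of 0.815, the wild-type value lay farther than the knockout value from the median of the 4 heart-specific arrays, and over all 11285 genes this share was 58.2%, but the knockout value also lay outside the range of these 4 arrays in 28 of the 65 (the wild-type value in 55). A wild-type heart that differs for a reason other than Kdm4a is therefore a candidate explanation for many of these differences, and a difference between the lines themselves stays open as untested. More atrial tissue in that heart could raise the atrial markers, of which a share of 0.667 was higher there by over 0.5. The low signals of Tbx5, Nr2f2 and Mybphl, under 2 times background, decide nothing. Of the 6 markers above that level, Myl4, Myl7, Sln, Nppa and Dkk3 were higher there by 0.92 to 2.94, and Stard10 was lower. Most of the brighter markers thus go with more atrial tissue. Expression within the ventricle could raise the same genes, so the 2 cannot be told apart. More blood could raise Slc4a1 and Alas2, but the median of 4 globin genes, wild type minus knockout, was -0.0935. Hbb-b2, the globin far from the highest value on the arrays (50962), differed by -0.29 between knockout and wild type against -2.41 for Slc4a1 and -1.88 for Alas2. It differed by -2.34 in the male pair, though, and the other globins reach 49016. The platelet genes Ppbp and Tubb1 were also higher in the general wild-type heart, as were 3 of 5 neutrophil and mast cell markers, with 2 lower. More blood and changes in single genes therefore cannot be told apart.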

How the results depend on the processing

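Background correction on the receptor probes with offset 16 or 50, the stricter background level and the list test between lines were added after the data were seen. The count of 0 genes over 3 pairs was the same in all 12 alternatives, without each pair in turn and without the pair block included. In the heart-specific comparison, 1 gene passed with offset 50, without the filter on dim probes and with an intensity trend, and 2 passed with the mean of a gene's probes. The difference between lines gave 15 genes with offset 16, 18 with offset 50 (4 of them higher), 21 without a filter, 19 with every probe on its own, 26 with the mean of probes, 28 with a trend and 0 for genes above background on all 6 arrays, where fewer genes remain. Between the sexes, 19 genes passed with offset 50 (6 higher in females), 2 with detection on all 6 arrays, 19 with every probe, 39 with the mean of probes and 22 with a trend. The general pair had 313 genes with offset 16 (121 higher), 114 with offset 50, 113 over single probes, 355 at 1.5-fold and 19 by limma with the spread of the heart-specific pairs. The correlation of the female and male effects became 0.00996 with offset 16 and 0.00336 with offset 50, where it had been -0.00742. Lists past the threshold over 3 pairs numbered 1 with offset 16, 2 with offset 50, 3 without the pair block, and 0 with an estimated correlation or fry. In the heart-specific and sex comparisons, 0 lists passed with either, and 0 between lines with an estimated correlation. Leaving out a pair gave -0.27 to 0.66 for Nppa, -0.45 to 0.36 for Nppb and -0.13 to 0.00568 for Myh6 over 3 pairs, and -0.38 to 0.16 for Myh7 and -1.41 to 0.37 for Acta1 over the heart-specific pairs. Myh6 in the general pair was -0.34 with the mean of its probes. The cause of these changes was not tested, and this includes the smaller number of genes or samples where named. Of the values of single named genes under other settings, 738 kept direction and side of the threshold, 9 came to pass, 8 no longer passed and 7 changed sign. General-pair values had no test and so no side to change. Genes picked for the same sign in every pair could not change sign when a pair was left out. The 738 are therefore no measure of robustness. Planned settings on the table of unassigned columns, and a slide block, were not run, and leaving out a pair leaves the sex and line comparisons without residual degrees of freedom. Dim genes, Kdm4a among them, are limited by signals near background.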

Other observations

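The tests of gene placement along chromosomes and of macrophage markers, with the bounds that decide them, were chosen only after the results were seen, whereas the tests of left-out pairs and of other splits of the arrays were set before.

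The 14 circadian clock genes did not pass as a list between female and male hearts of the heart-specific line (adjusted p = 0.304). When adjusted over the list alone 3 members passed, against 0 over all genes. These were the clock output gene Dbp (female minus male 1.12 ± 0.17, SE), Per1 (0.81 ± 0.17) and Per2 (0.74 ± 0.20), whereas Arntl, which drives them, had a difference of -0.59 ± 0.20 and did not pass.

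The chromatin genes nearest in function to Kdm4a showed small differences. Among 22 measured histone lysine demethylase genes, the related Kdm4b and Kdm4c, named after their values were seen, differed little. Kdm4b differed by 0.01 ± 0.19 and Kdm4c by -0.05 ± 0.14 (SD, n = 3 pairs). Kdm5b (-0.21 ± 0.13) and Kdm3a (-0.19 ± 0.18) had the most negative means. The list did not pass over 3 pairs (adjusted p = 0.983), nor did the 13 genes of H3K9 and H3K36 methylation (adjusted p = 0.598). Heat shock genes had a mean of -0.20 ± 0.03 (SD, n = 3 pairs) without passing (adjusted p = 0.0889), and the 14 members other than Hspb7 had a mean of -0.06, with Hspb7 the 1 member past the test when adjusted over the list alone (-2.11 ± 1.196) and Hspa4 lower in every pair (-0.24 ± 0.12).

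In the general pair, whose labels give no sex, Eif2s3y had an intensity of 1116 in the wild type and 1380 in the knockout, and Xist of 101 and 104. Both hearts thus had the sex-linked signals of males. In the heart-specific line, Eif2s3y had a mean of 1296 in males and 101 in females, and Xist of 105 and 1590. Gdpd3 was at 133 in the general wild type, 114 and 133 in the males, and at 1378 in the general knockout and 1232 and 1051 in the females. High Gdpd3 was therefore also seen in a heart with male sex-linked signals.

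The genes with the widest differences in both heart-specific pairs included 10 of 50 on the chromosome of Kdm4a. A share of 0.0178 of 11266 circular shifts of the effects along the genome gave as many there, but a share of 0.142 gave as extreme an excess on any chromosome, and with the 100 most changed genes 0.0763 gave as many on that of Kdm4a, so the placement and chance cannot be told apart once the chromosome and the number of genes were taken from the observation. A segment of other strain origin carried along with the targeted Kdm4a allele could give such a pattern, and 0 of the 100 tested genes nearest to Kdm4a were among the 50 most changed. Since 68.7% of the shifts also gave 0 there, this cannot be told apart from a segment that begins farther away. Arhgef19, Hspb7, Tmem51, Nppa, Fbxo44, Klhl21 and Isg15 lay on the same side of Kdm4a, 221 to 335 tested genes from it. Whether genes crowd in that stretch by more than chance was not tested. In the general knockout 5 of the 10 genes had the same sign as in the heart-specific pairs. These were Klhl21 (-0.84), Hspb7 (-0.83), Isg15 (0.38), Fbxo44 (-0.06) and Arhgef19 (-0.05), with the values of Fbxo44 and Arhgef19 very small. The opposite sign was seen for the other 5, Nppa (-1.05), Acer2 (0.50), Ctnnal1 (0.45), Tmem51 (-0.36) and Pde4b (-0.34). A dependence on Kdm4a shared by all 10 is thus not seen in both lines, while one for some of them stays open.

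Interferon response genes had a mean of 0.28 in the female and 0.31 in the male heart-specific pair, and of 0.01 in the general pair. The interferon mean lay above the macrophage marker mean in each pair, by 0.23 ± 0.07 (SD, n = 3 pairs). In the general pair that gap of 0.31 came from lower macrophage markers (-0.30). Macrophage markers were higher by 0.06 in the female and 0.15 in the male pair, and 2 lists need not shift equally with a gain of cells. More macrophages as the whole cause can therefore not be excluded by these means. A single pair as the source is argued against by the largest camera p after leaving out a pair, 0.000354. That p holds at the preset correlation only, and over 3 pairs the list has an adjusted p of 0.886 with an estimated correlation and of 0.962 with fry. With 2 residual degrees of freedom a list could hardly pass either of these, so they decide little here. Among the 10 splits of the 6 arrays into 3 and 3, 2 gave a list mean as far from 0, with 0.20 for the real split and 0.26 for the highest other. That other split did not part every pair. Among the splits that did, the real one lay farthest from 0, and the others gave -0.007, -0.192 and 0.015. All 10 splits, and the fewer that part every pair, are too few for a share under 0.05. A response to Kdm4a loss and an unrecorded difference in exposure or housing between the hearts stay open, and neither was tested.

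Without the pair term, the real split gave 0 genes past the threshold, so that all 10 splits necessarily gave as many and the comparison says nothing, and the highest other gave 3. For lists the real split gave 3, 9 of the 10 splits gave as many, and the highest other gave 12. A structure among the hearts that does not follow genotype could give such counts. A preset correlation that is too low could give them as well. An estimated correlation left 0 lists over 3 pairs, but with 2 residual degrees of freedom hardly any list could pass. Neither explanation was tested. With the pair block, 4 splits part all 3 pairs. The real one gave 0 genes and 6 lists, and the others 0 to 2 genes and 5 to 9 lists. The splits are too few for a share under 0.05.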
